A study of Mus musculus with 8 samples.

How the data were processed

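RNA-seq libraries of the chromatin and cytoplasmic fractions of mouse embryonic fibroblasts were analysed, with 1 library per fraction and condition. Groups were taken from the sample titles. Per the labels' protocols, the cytoplasm was collected over a sucrose cushion, nuclei were washed and lysed with a buffer containing urea, the soluble nuclear part was removed, and the remaining pellet was used as chromatin. The same protocols describe gel selection of short RNA fragments before library preparation.

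The deposited files hold 1 RPKM value (reads scaled to gene length and to the library total) per Ensembl gene identifier, computed by the authors. Genes without a read are not listed. Cutadapt and STAR and the mouse build GRCm38 are named, per the submitters' processing notes, without versions. The read counter, the annotation release, strand handling and the treatment of reads that match several genes are not given in the sources used here. Genes that overlap another gene or share sequence with a copy are therefore uncertain.

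The values were whole multiples of the worth of 1 read, so library totals, reads and gene lengths were recovered from them. For many genes with few reads, the inverse of RPKM in units of single reads and bases is a whole number (tolerance 0.002) that the library total divides. The greatest common divisors of 20000 random pairs of such numbers were counted, and the largest one with at least 0.5 of the most frequent one's count was taken as the total. This rule replaced the most frequent divisor after that choice had returned a wrong total for 1 of 4 simulated libraries. Both rules gave the same total for all 4 real libraries. Reads and length per gene were then the smallest whole numbers that gave the values in all 4 libraries. No gene had a relative error above 1e-12. Reads that share a factor with the gene's length come out too small, together with that length. The recovered reads summed to 98.4%, 98.5%, 99.6% and 99.7% of the totals (chromatin without and after heat shock, then cytoplasm). Ratios between libraries are not affected by this, but a span class may be too short and a counting interval too wide for such genes.

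The recovery was tested on simulated data. In 10 simulated sets of 4 libraries with seeds not used for choosing the rule, 40 of 40 totals were recovered, and reads and length were exact for 91.6% to 92.2% of at least 26946 genes. Recovery was less exact in the simulations of 2 libraries used for the 2-fold rule, with exact reads for 85.3% of genes in chromatin and 85.1% in cytoplasm (both 83.7% at 100 reads or more) and 93.2% and 97.5% of reads recovered. For the chromatin heat shock comparison (25752 simulated genes), the 2-fold rule found 100% of 100 genes with a true log2 change of 3 and 86% of 100 with 1.5, and it called 26 of 6096 unchanged genes. For the cytoplasmic comparison (20362 simulated genes) it found 100% and 90%, and called 28 of 2344 unchanged genes. The changed genes were drawn only from genes above a minimum of expected reads and RPKM, so detection among genes with few reads was not simulated. Genes were kept on their mean RPKM over the 2 simulated libraries, where the real filter used 4. These rates therefore do not carry over directly to the real lists. The simulation held counting error alone and no variation between cultures.

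The implied lengths ran from 15 bp to 4.43 Mb with a median of 11266 bp. Among 2537 genes over 100 kb, 8.75% had a length equal to the span of some gene in the RefSeq annotation of GRCm38.p6, against a mean of 1.73% when lengths were shifted by 1 to 10 bp. The RPKM values are therefore treated as relative to whole gene spans with introns. An RPKM on this basis understates spliced RNA of long genes relative to short ones, so levels were compared between libraries for the same gene, and span classes by ratios or shares of reads. The 6 span classes were chosen after the lengths were recovered.

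For each comparison, log2((RPKM + 1)/(RPKM + 1)) was computed per gene, with a pseudocount of 1 RPKM, which understates differences of genes with low values. Genes were kept at a mean of at least 1 RPKM over the 4 libraries. A kept gene with no read in one of the compared libraries got no ratio and was counted apart. Genes at least 2-fold higher or lower were counted. With 1 library per group, no significance test or replicate spread could be given. Folds printed for single genes are RPKM ratios without a pseudocount, with exact 95% Clopper-Pearson intervals from the recovered reads. Reads without molecular identifiers are not independent molecules, so these cover counting error only. Intervals over genes came from 2000 bootstrap resamples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

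The rule for single genes, the gene lists, the comparisons and most alternative settings were fixed before the data were examined. The rule took kept genes at 5 RPKM or more in at least 1 of the compared libraries and above 0 in both, and then the 10 highest and the 10 lowest log2 ratios of RPKM + 1. Its further parts need gene names: leaving out predicted genes, pseudogenes, small structured RNAs and mitochondrial genes, and always reporting a set of heat shock, nuclear RNA and m6A genes. Of the 28785 identifiers, 0 could be paired with a name in the reference table used here, so these parts and the 44 gene lists, with their markers of other cell types, were not applied. The classes those exclusions would have removed can therefore be among the genes described. Identifiers are given for the first gene in each direction of both heat shock comparisons.

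The alternatives were pseudocounts of 0.1 and 5 RPKM, no filter, a mean of at least 5 RPKM, rescaling to the same RPKM sum, setting the median log2 ratio to 0, leaving the 10 genes with the highest mean RPKM out of the scale, taking unlisted genes as 0, and a threshold of 3-fold. A ratio of recovered shares of reads without pseudocount (at least 100 reads over both libraries) and a restriction to spans over 1 kb were added after seeing the data. The 2 m6A immunoprecipitation libraries and their 2 inputs were not analysed here.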

Results

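RNA was measured in mouse embryonic fibroblasts, connective tissue cells grown from mouse embryos, that were wild type for Tsc2 and on a C57BL/6J background. Cells were either left unstressed or heat shocked at 42 °C for 1 h and returned to 37 °C for 3 h. They were then separated into a cytoplasmic fraction and a chromatin pellet, and RNA-seq was made from each fraction, which gave 4 libraries with 1 library per group. No difference between these libraries therefore has a replicate check, no test was made, and the values describe these libraries. The series also holds 2 chromatin libraries immunoprecipitated for N6-methyladenosine (m6A, a methylated base of RNA) and their 2 inputs, which were not analysed here.

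The library totals implied by the RPKM values were 18364642 reads for chromatin without heat shock, 19536459 for chromatin after heat shock, 8292312 for cytoplasm without heat shock and 11131382 for cytoplasm after heat shock. At least 1 read was listed for 22804, 26129, 16818 and 21167 genes, respectively. Of the 28785 genes listed in any library, 14994 were listed in all 4, and 4688 had a mean of at least 1 RPKM. The files identify genes by Ensembl identifier and do not pair these with names, so genes are described by their span, the gene length implied by the RPKM values, and 4 are given by identifier. Intervals for single genes are exact 95% intervals on reads and cover counting error only. Those for shares or medians of sets of genes take genes as the units and do not cover variation between libraries.

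A single gene with a span of 1831 bp held the most reads in every library. It took 8.01% of reads in chromatin without heat shock (95% Clopper-Pearson interval 8.00 to 8.02) and 14.0% after heat shock (14.0 to 14.1). In cytoplasm it took 44.6% (44.6 to 44.7) and 47.4% (47.4 to 47.5). The 10 genes with the most reads in each library together held 21.8% and 32.6% of chromatin reads and 75.9% and 79.8% of cytoplasmic reads, without and after heat shock.

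**Figure D1:**
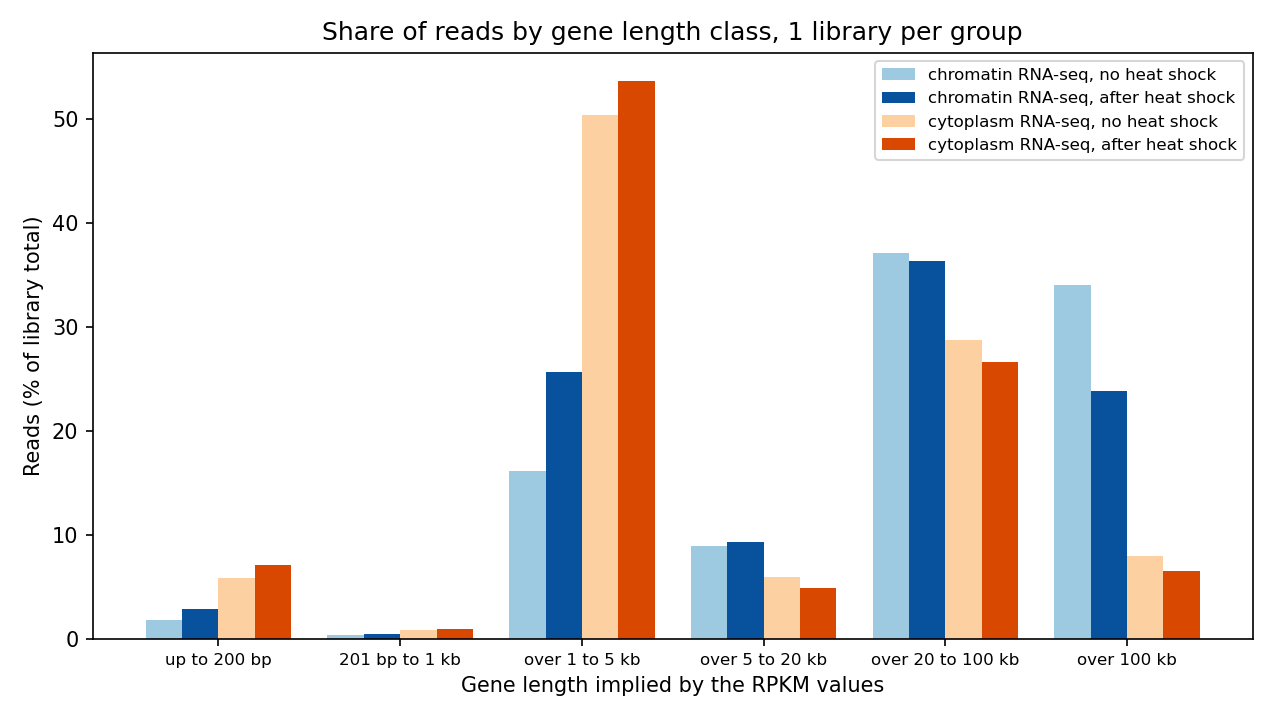
Share of each library's reads (y axis, percent of the library total) in 6 classes of gene span (x axis), 1 bar per library. Genes with spans over 100 kb held 34.0% of chromatin reads without heat shock and 23.8% after it, against 7.91% and 6.52% in cytoplasm. In cytoplasm a single gene of 304627 bp held 3.53% and 3.34% of all reads, against 0.45% and 0.68% in chromatin.

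The first comparison set chromatin RNA after heat shock against chromatin RNA without it. Genes with short spans had higher ratios after heat shock than genes with long spans. On the deposited scale the median log2 ratio was 0.40 for spans up to 200 bp, 0.39 for over 200 bp to 1 kb, 0.30 for over 1 to 5 kb, 0.13 for over 5 to 20 kb, 0.02 for over 20 to 100 kb and -0.25 for over 100 kb, while after rescaling each library to the same RPKM sum all 6 medians were below 0, from -0.02 for over 200 bp to 1 kb to -0.89 for over 100 kb. Genes with spans over 100 kb held 34.0% of reads without heat shock and 23.8% after it, and those of over 1 to 5 kb held 16.1% and 25.7%. Most of the latter gain was in 2 genes, the one of 1831 bp (8.01% and 14.0%) and one of 3329 bp (6.71%, 6.70 to 6.72, and 9.70%, 9.68 to 9.71). Outside the 10 genes with the highest mean share of reads over the 4 libraries, spans of over 1 to 5 kb held 1.83% and 2.91% of the remaining reads and spans over 100 kb 43.6% and 35.1%. With recovered reads in place of RPKM + 1 the class medians ran from 0.96 for the shortest to -0.48 for the longest, and those for over 5 to 20 kb and over 20 to 100 kb were below 0 (-0.03 and -0.22). The rank correlation of the log2 ratio with span was -0.25 across genes, which are not independent replicates. Of the 4635 genes compared, 481 were at least 2-fold higher after heat shock and 216 at least 2-fold lower. The median span was 2803 bp among the former and 11814 bp among the latter.

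Single genes were ranked by the log2 ratio of RPKM + 1, which shrinks ratios of genes with low values, so the order differs from that of the plain folds. The first gene higher in chromatin after heat shock, ENSMUSG00000064350, has a span of 67 bp and had 243 reads after heat shock against 1 without, a 228-fold difference with an interval of 40.6 to 9059. Without names, small structured RNAs and mitochondrial genes could not be left out of this ranking. Of the first 10 higher genes, 6 had spans of up to 200 bp. The others included a gene of 22090 bp with 46019 reads against 723 (59.8-fold, 55.6 to 64.5) and a gene of 1645 bp with 1397 against 8 (164-fold, 83.1 to 381). A gene of 6181 bp had 3219 reads after heat shock and 2 without (1513-fold, 418 to 12498). The first lower gene was ENSMUSG00000084498, with a span of 119 bp and 37 reads after heat shock against 250 without (7.19-fold lower, 5.07 to 10.4). Others among the first 10 lower genes had spans of 6611 bp (14.3-fold lower, 11.6 to 17.9), 87111 bp (7.51-fold lower, 7.26 to 7.78) and 67681 bp (5.90-fold lower, 5.80 to 6.00). Over all genes the median log2 ratio was 0.12, and the balance of directions depended on the scale. Genes at least 2-fold higher made up 69.0% of those past 2-fold on the deposited scale, 25.3% on the rescaled one (median log2 ratio -0.42) and 57.6% when the median was set to 0.

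In cytoplasm fewer genes passed 2-fold than in chromatin on the deposited scale. Of 4505 genes, 153 were at least 2-fold higher after heat shock and 110 at least 2-fold lower, and the median log2 ratio was -0.25. Genes of over 200 bp to 1 kb passed 2-fold most often on this scale, with 51 of 170 at least 2-fold lower and 17 at least 2-fold higher. Among genes of over 100 kb, 0 of 239 passed 2-fold on this scale, where the pseudocount shrinks ratios of low values, while with recovered reads 381 of 1058 were at least 2-fold lower and 62 at least 2-fold higher. On the RPKM + 1 scale all 6 span classes had medians below 0, from -0.32 for over 200 bp to 1 kb to -0.16 for spans up to 200 bp and over 100 kb, but with the median of all genes set to 0 those for up to 200 bp, over 20 to 100 kb and over 100 kb were above 0 (0.10, 0.03 and 0.09). With recovered reads the order of the classes differed, with medians of 0.05 for up to 200 bp, -0.90 for over 200 bp to 1 kb, -0.44 for over 1 to 5 kb, -0.56 for over 5 to 20 kb, -0.62 for over 20 to 100 kb and -0.78 for over 100 kb.

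The first gene higher in cytoplasm after heat shock was ENSMUSG00000027517, a gene of 9700 bp with 8729 reads after heat shock against 178 without (36.5-fold, 31.5 to 42.6). The gene of 1645 bp among the first 10 higher in chromatin was also among those in cytoplasm, with 649 reads against 9 (53.7-fold, 28.1 to 118). So was a gene of 77 bp, at 2574 reads against 89 in cytoplasm (21.5-fold, 17.4 to 26.9) and 164 against 3 in chromatin (51.4-fold, 17.3 to 252). These 2 genes were the overlap between both sets of 10. All of the first 10 lower genes had spans of 378 to 748 bp. The first of them, ENSMUSG00000052565, had a span of 744 bp and 42 reads after heat shock against 522 without (16.7-fold lower, 12.2 to 23.4). Genes at least 2-fold higher made up 58.2% of those past 2-fold, 41.6% after rescaling to the same RPKM sum (median log2 ratio -0.40) and 73.6% with the median set to 0. The rank correlation of the log2 ratio with span was 0.11 here, and its sign changed with the pseudocount, the filter and the scale.

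**Figure D2:**
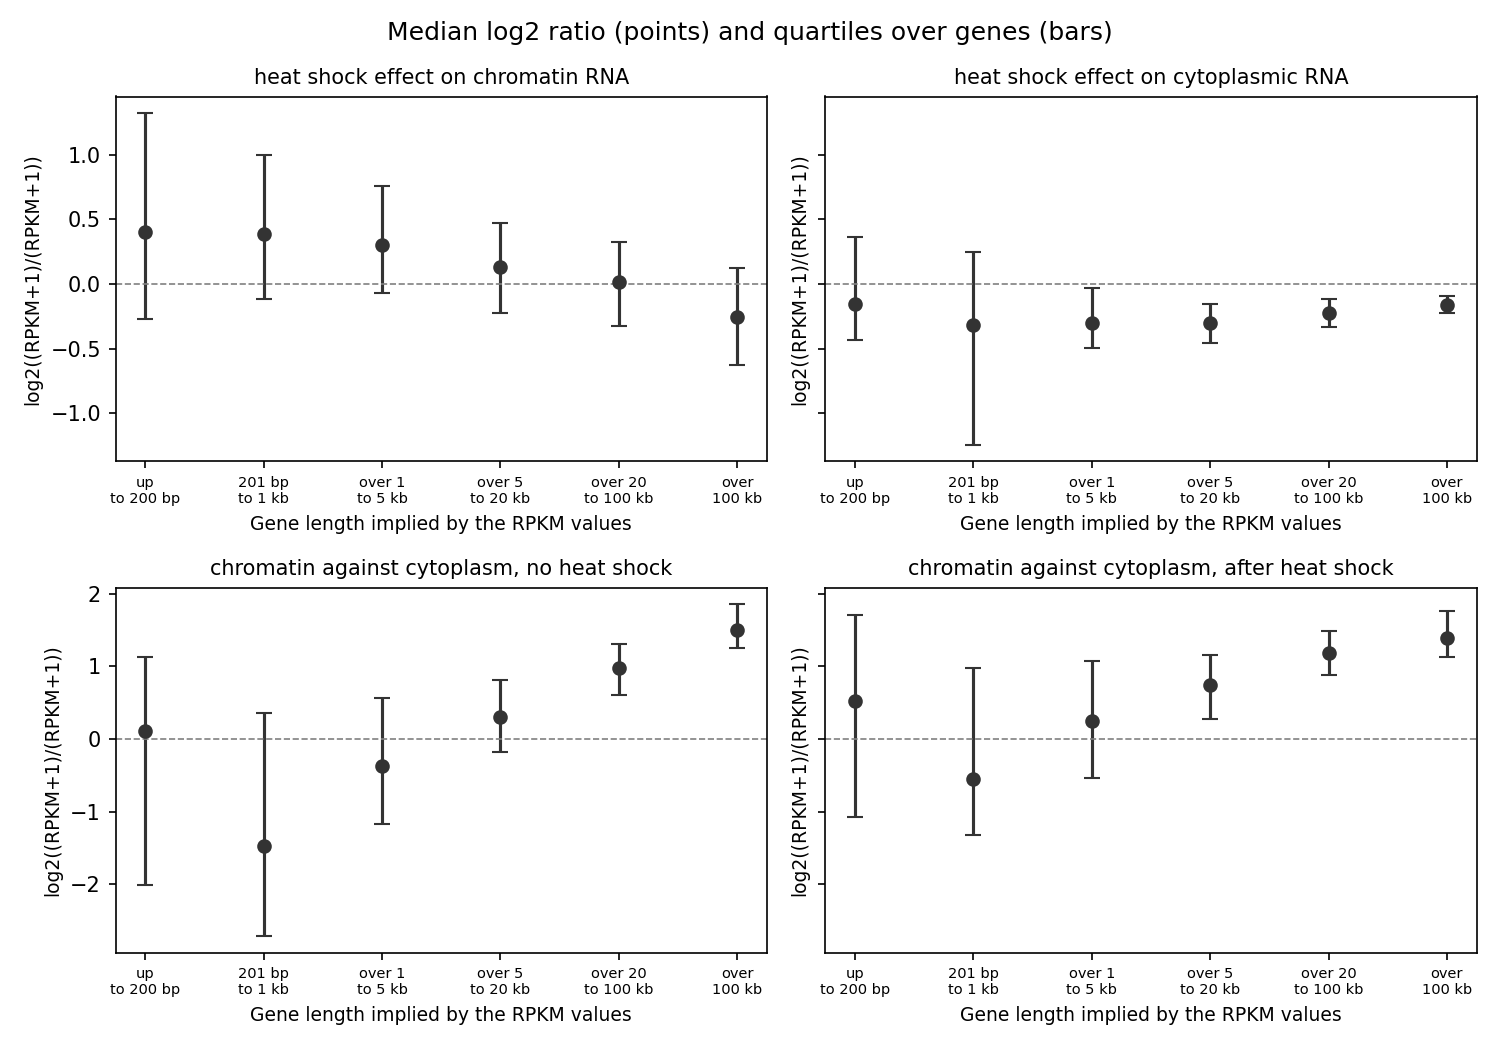
Median log2 ratio of RPKM + 1 (points, y axis) with the lower and upper quartiles over genes (bars) in 6 classes of gene span (x axis), 1 panel per comparison. The chromatin median after against without heat shock went from 0.40 in the shortest class to -0.25 in the longest, and every cytoplasmic median was below 0 on the deposited scale, but signs of class medians change with the scale and their cytoplasmic order with the pseudocount.

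Chromatin was then compared with cytoplasm in unstressed cells. The median gene of both span classes over 20 kb was higher in chromatin on each of the 4 scales used, and that of over 200 bp to 1 kb was lower. For spans over 100 kb the median log2 ratio of chromatin to cytoplasm had a bootstrap interval over genes of 1.45 to 1.59, and 213 of 239 genes were at least 2-fold higher in chromatin and 3 at least 2-fold lower. The median was 0.98 for over 20 to 100 kb, 0.30 for over 5 to 20 kb, -0.37 for over 1 to 5 kb, -1.48 for over 200 bp to 1 kb and 0.12 for up to 200 bp, and those for up to 200 bp, over 1 to 5 kb and over 5 to 20 kb changed sign among the scales. Over all 4512 genes, 1460 were at least 2-fold higher in chromatin and 529 lower, and the rank correlation of the ratio with span was 0.52 across genes.

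The first gene toward chromatin was ENSMUSG00000084498, the first lower gene of the chromatin heat shock comparison, with 250 chromatin reads against 3 (37.6-fold, 12.7 to 184); both comparisons use the unstressed chromatin library. Among the other first 10, a gene with a span of 6983 bp had 209301 chromatin reads against 5299 in cytoplasm (17.8-fold, 17.4 to 18.3). A gene of 139591 bp had 81491 against 2108 (17.5-fold, 16.7 to 18.2). Of the first 10 toward cytoplasm, 9 had spans of up to 200 bp, and these 10 genes were 82.1-fold to 376-fold lower in chromatin. The balance of directions moved with the scale, since RPKM is relative to each library's own total. Genes higher in chromatin were 73.4% of those past 2-fold on the deposited scale, 94.9% after rescaling to the same RPKM sum, 37.9% with the median set to 0 and 46.8% when the 10 genes with the highest mean RPKM were left out of the scale. Medians over all genes were 0.58, 2.01, 0 and 0.09 on these scales.

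After heat shock, 2096 of 4575 genes were at least 2-fold higher in chromatin than in cytoplasm and 317 at least 2-fold lower. Class medians of the log2 ratio were 1.39 for spans over 100 kb, 1.19 for over 20 to 100 kb, 0.74 for over 5 to 20 kb, 0.25 for over 1 to 5 kb, -0.55 for over 200 bp to 1 kb and 0.53 for up to 200 bp, and those for spans up to 20 kb changed sign among the scales. The rank correlation with span was 0.40 across genes. The first gene toward chromatin was one of 20771 bp, with 81804 chromatin reads against 581 in cytoplasm (80.2-fold, 73.9 to 87.2). The same gene had 49887 against 1818 without heat shock (12.4-fold). The first gene toward cytoplasm was one of 1410 bp, with 18 chromatin reads against 1481 (144-fold lower in chromatin, 91.0 to 244). Genes higher in chromatin were 86.9% of those past 2-fold, 97.1% after rescaling to the same RPKM sum, 33.4% with the median set to 0 and 70.6% without the 10 highest genes in the scale. Medians over all genes were 0.92, 1.95, 0 and 0.59 on these scales.

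Across the 4688 kept genes, log2(RPKM + 1) in chromatin and cytoplasm correlated at r = 0.67 without heat shock and r = 0.77 after it. Chromatin after heat shock also correlated at r = 0.77 with cytoplasm without heat shock. The 2 chromatin libraries correlated at r = 0.83 and the 2 cytoplasm libraries at r = 0.94. Rank correlations of the same genes were lower. Chromatin against cytoplasm gave 0.24 without heat shock and 0.37 after it, and chromatin after heat shock against cytoplasm without it 0.35. The 2 chromatin libraries gave 0.56 and the 2 cytoplasm libraries 0.85. All of these are correlations across genes, which are not independent replicates.

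The last comparison asked whether a gene's difference after heat shock was the same in both fractions. Among 4473 genes with reads in all 4 libraries, 737 had a log2 ratio at least 1 higher in chromatin than in cytoplasm and 202 at least 1 higher in cytoplasm. The 2 log2 ratios correlated at r = 0.29 across genes. At least 2-fold higher in both fractions were 51 genes, against 13.6 for independent lists, and 11 were lower in both, against 4.59. Opposite directions past 2-fold were seen in 14 genes higher in chromatin and lower in cytoplasm and in 1 gene the other way round. On the deposited scale the median difference was 1.13 for spans of over 200 bp to 1 kb and -0.11 for spans over 100 kb. With the median of each fraction set to 0, the counts were 359 and 381, and after rescaling to the same RPKM sum 491 and 545.

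**Figure D3:**
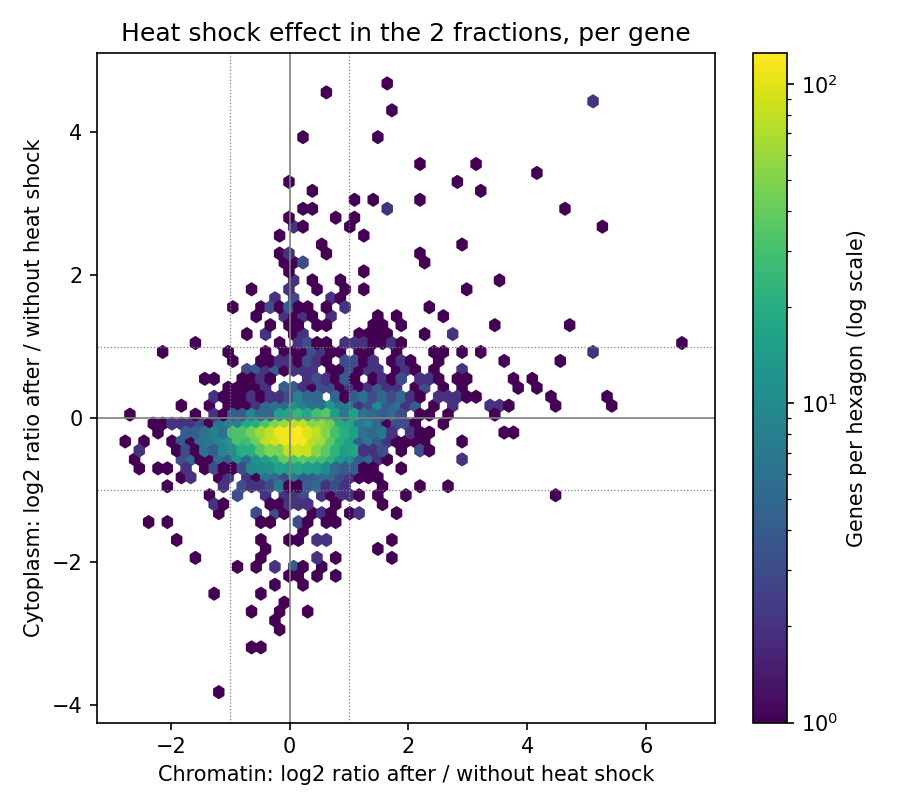
Log2 ratio of RPKM + 1 after against without heat shock in chromatin (x axis) and cytoplasm (y axis) for 4473 genes, shaded by genes per hexagon on a log scale; dotted lines mark 2-fold. The 2 ratios correlate at r = 0.29 across genes, and the spread is wider in chromatin.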

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

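The tests of cytoplasmic carry-over, genomic DNA and transcription were fixed before their results were seen, apart from carry-over for spans of over 1 to 5 kb and for the loss of long spans, and these tests, the other choices of genes and the test on the 10 highest genes were chosen after.

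In 5 of 6 span classes the median gene was higher after heat shock in chromatin and lower in cytoplasm, among genes with reads in all 4 libraries. The chromatin minus cytoplasm difference of log2 ratios had a median of 0.81 for spans up to 200 bp (0.68 and -0.16 in the 2 fractions), 1.13 for over 200 bp to 1 kb (0.30 and -0.36), 0.59 for over 1 to 5 kb (0.30 and -0.30), 0.43 for over 5 to 20 kb (0.13 and -0.30) and 0.23 for over 20 to 100 kb (0.02 and -0.23). With 1 library per group these differences were not tested. The signs depend on the scale: after rescaling to the same RPKM sum the chromatin median of these genes was 0.17 for spans up to 200 bp and below 0 in the other classes, from -0.03 to -0.89. The difference for over 20 to 100 kb then turned to -0.21, and to -0.13 with the median of each fraction set to 0, and that for over 5 to 20 kb was 0.07 and 0.06. For the 3 shorter classes it stayed above 0 on the 4 scales used, at 0.22 or more.

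The shift of chromatin reads from long to short spans after heat shock has several candidate explanations. Genomic DNA in the unstressed chromatin library would cover all spans evenly, yet 54.0% of the 2537 genes over 100 kb (interval 52.0 to 56.0) had fewer than the 2.95 reads per kb that the lost 10.2 percentage points need, which argues against DNA as the whole cause. Carried-over cytoplasmic RNA would have to form 39.1% of the heat-shocked library to lower spans over 100 kb from 34.0% to 23.8% of reads. If it held no such spans, 30.0% would do. The median share over 75 genes high in cytoplasm was 17.2% (13.7 to 24.8, an interval over genes and not over libraries). The upper quartile, 36.5%, reached the needed range, and the lower was 8.26%. In the 8 genes with at least 1% of both cytoplasmic libraries and higher there, the share was 5.12% to 21.5%. For the median gene and these 8 genes, this argues against carry-over of RNA with a cytoplasmic composition as the whole cause. It leaves open that carry-over may add to it, and it assumes no other change of these genes after heat shock. The test fixed before used genes at least 8-fold higher in unstressed chromatin than in cytoplasm. That choice uses the unstressed chromatin library, the denominator of the ratio, so the medians below are not independent of it. Their median log2 ratio for over 5 to 20 kb exceeded that for over 100 kb by 0.14 (-0.07 to 0.33). This lay in the range set for carry-over, but the interval reached past it, so it decides nothing. For over 1 to 5 kb, a class chosen after, the excess was 0.72 (0.55 to 0.91). This lay above the range set for carry-over as the whole cause for these 109 genes. Since the class was picked after and the genes on the denominator, it is weak evidence against it. Medians of the other classes, from the shortest, were -0.72 (7 genes), -0.85 (5 genes) and -0.83 (over 20 to 100 kb), against -0.94 for over 100 kb. With genes chosen on both conditions or on the heat-shocked libraries the excesses were 0.82 and 1.05 for over 1 to 5 kb, and 0.53 and 1.01 for over 5 to 20 kb. These choices use the heat-shocked chromatin library, the numerator of the ratio, and add no support. A fall in transcription of long genes stays open, since it cannot be told apart from a difference between cultures with 1 heat-shocked chromatin library.

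Chromatin correlated more highly with cytoplasm after heat shock (r = 0.67 without and 0.77 after, across genes). By the ratios it was not closer on the deposited scale, where the median log2 ratio of chromatin to cytoplasm went from 0.58 to 0.92. Genes higher and lower past 2-fold went from 1460 and 529 to 2096 and 317. With the median set to 0 they went from 546 and 893 to 392 and 781. If one common share of cytoplasmic RNA were the whole cause of the higher correlation, genes at least 8-fold higher in cytoplasm with at least 200 cytoplasmic reads would all show that share. Of 75 such genes 73 were higher in chromatin after heat shock, a count that is not independent of choosing them for low values in the unstressed chromatin library. The upper quartile of the share per gene was 4.41 times the lower (36.5% against 8.26%, interval of the ratio 2.57 to 7.89). This argues against a single even share as the whole cause. An even share together with other changes of single genes is left open. Carry-over that differs between kinds of RNA may still account for part of the higher correlation and was not tested, nor was a change of RNA retention on chromatin.

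The median cytoplasmic gene had a smaller share of reads after heat shock, with a log2 ratio of -0.60 over 6647 genes with at least 100 reads. A few genes taking more of the counts could lower all others. With the 10 genes of highest mean RPKM left out of the scale the median was -0.45 (-0.47 to -0.44), so these 10 genes may account for part of the shift and not for all of it. With the 100 most read cytoplasmic genes left out of the scale it was -0.19. No biological explanation was tested.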

How the results depend on the processing

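The ratio of recovered reads and the restriction to spans over 1 kb were chosen after seeing the data. Paired values are genes higher, then lower, past 2-fold, and the cause of a change was not tested unless given. No paired analysis was possible because each group holds 1 library. Of 220 alternative values for 23 results, 96 stayed close to the reported value, 117 moved and 7 reversed. Some of the 96 could not have differed. Setting the median shifts every log2 ratio alike and leaves correlations unchanged, and filters or unlisted genes leave a single gene's ratio unchanged. Close was also a wide range for counts. Both 641 and 327 were taken as close to 481 genes higher in chromatin after heat shock. The 96 is therefore not a measure of stability. The 10 alternatives for gene lists were not run, since identifiers were not paired with names, and the scale without the highest genes left out only the 10 genes of highest mean RPKM for the same reason. Depth limits genes with few reads, whose intervals span several fold.

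For heat shock in chromatin (481 and 216), the counts were 728 and 415 with a pseudocount of 0.1 RPKM, 170 and 52 with 5 RPKM, 205 and 48 at a mean of at least 5 RPKM (fewer genes) and 209 and 67 at 3-fold. Rescaling to the same RPKM sum gave 965 lower. Recovered reads gave 1569 and 2143 over more genes, and spans over 1 kb 304 higher. The median log2 ratio of 0.12 reversed to -0.42 on rescaling and -0.13 with recovered reads. The rank correlation with span, -0.25, stayed negative throughout, at -0.20 without a filter, -0.22 at a mean of 5 RPKM and -0.21 with recovered reads.

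For heat shock in cytoplasm (153 and 110), the counts were 236 and 431 with 0.1 RPKM, 68 and 50 with 5 RPKM, 65 and 66 at a mean of 5 RPKM and 80 and 44 at 3-fold. Rescaling gave 184 lower, a median of 0 gave 73 lower and spans over 1 kb 41 lower. Recovered reads gave 351 and 1258. The rank correlation with span, 0.11, reversed to -0.10 with 0.1 RPKM, -0.18 at a mean of 5 RPKM, -0.0202 without the highest genes in the scale and -0.20 with recovered reads. It was 0.20 with 5 RPKM, 0.16 on rescaling, 0.0719 with unlisted genes as 0 and 0.18 for spans over 1 kb.

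For chromatin against cytoplasm without heat shock (1460 and 529), the counts were 244 and 288 with 5 RPKM, 206 and 323 at a mean of 5 RPKM, 3461 and 187 on rescaling, 546 and 893 with a median of 0, 868 and 985 without the highest genes and 540 and 311 at 3-fold. Recovered reads gave 6859 higher and spans over 1 kb 326 lower. The median reversed to -0.53 at a mean of 5 RPKM. The rank correlation, 0.52, was 0.48 with 5 RPKM, 0.29 without a filter, 0.28 at a mean of 5 RPKM, 0.44 with unlisted genes as 0, 0.59 with recovered reads and 0.55 for spans over 1 kb.

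After heat shock (2096 and 317), they were 325 and 167 with 5 RPKM, 266 and 184 at a mean of 5 RPKM, 3693 and 111 on rescaling, 392 and 781 with a median of 0 and 775 and 161 at 3-fold. Leaving out the highest genes gave 630 lower, spans over 1 kb 165 lower and recovered reads 7974 higher. The rank correlation, 0.40, was 0.49 with 0.1 RPKM, 0.32 with 5 RPKM, 0.13 without a filter, 0.24 at a mean of 5 RPKM, 0.46 without the highest genes, 0.34 with unlisted genes as 0, 0.47 with recovered reads and 0.44 for spans over 1 kb.

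For the difference between fractions (737 more positive in chromatin, 202 in cytoplasm), 0.1 RPKM gave 1366 in chromatin, 5 RPKM 228 and 61, a mean of 5 RPKM 302 and 48, rescaling 491 and 545, and medians of 0 359 and 381. The correlation of 0.29 was 0.38 with 0.1 RPKM, 0.21 without a filter and 0.41 at a mean of 5 RPKM. The 4 genes given by identifier kept their direction under every setting computed for them. The filters and the treatment of unlisted genes could not change their ratios, so these settings do not test them.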

Other observations

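The tests reported here were chosen after the results were seen, apart from the share of cytoplasmic RNA per gene.

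Of the 10 genes with the highest ratios in chromatin after against without heat shock, 5 were also among the 10 with the highest ratios toward cytoplasm in unstressed cells. They had spans of 67 to 69 bp, were 83.0-fold to 376-fold lower in chromatin than in cytoplasm without heat shock, and were 38.5-fold to 228-fold higher in chromatin after it. In cytoplasm they were 1.17-fold to 2.09-fold higher after heat shock, and they stayed 2.64-fold to 11.1-fold lower in chromatin. Both lists use the unstressed chromatin library, so a low value there puts a gene toward the top of each. As a hypothesis, RNA carried over from the cytoplasm may be one source of their reads, which would correspond to shares of 17.2% to 60.6% per gene. These shares restate that assumption and do not test it. The 5 genes were not named, so small structured RNAs or mitochondrial genes can be among them. The quartiles over 75 genes high in cytoplasm, 4.41 times apart, argue against one even share as the whole cause. An even share together with other changes of single genes is left open.

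More genes were listed after heat shock in both fractions. At the depth of the shallowest library, 20105 genes would be listed for chromatin without heat shock and 22941 after it, and 16818 and 19958 for cytoplasm. In chromatin, 127 genes had no read without heat shock and at least 20 reads after it, while 0 genes went the other way. Of these, 103 had a read in a cytoplasmic library. The highest had 785 reads and a span of 14405 bp, at least 246-fold higher against a floor of 3 reads. In cytoplasm, 42 genes went from no read to at least 20 and 0 the other way, the highest with 304 reads and a span of 2803 bp, at least 75.5-fold higher. These genes were singled out after their values were seen.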
